A study of Mus musculus with 25 samples.

How the data were processed

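Small RNA libraries from brain hemispheres of male C57BL/6 mice, a common inbred laboratory strain, were analysed at 5 ages: 2, 9, 15, 24 and 30 months, with 5 libraries per age and 25 in all. Per the labels' protocols, total RNA was extracted and libraries were made with the TruSeq small RNA kit, which ligates adapters to short RNAs with a free phosphate at the 5' end and carries no molecular identifiers. The titles carry a different animal number for each library, so the replicates were taken as separate animals. Ages were taken from the labels; replicate numbers follow the order of deposition and pair no animals across ages.

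The authors deposited whole-number counts of reads per miRNA precursor hairpin, with both arms of a hairpin counted together, for 1193 precursors in 25 libraries. The submitters' processing notes name bcl2fastq 1.8.4, Trimmomatic 0.36 and SAMtools 1.3.1-9; the aligner, the counting tool, the treatment of reads with several matches, the use of strand and the genome build are not given in the sources used here. Column names in the deposited count table carry the sequencing lane, and the 6 lanes each hold libraries of several ages. Lane was treated as a technical batch, and 4 lanes held both ages of each pair compared. Every column was used.

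Total counts per library ranged from 3.78 to 9.52 M (mega-reads), with a median of 5.61 M. Because PCR reads without molecular identifiers are not independent molecules, precision was taken from the spread between animals and not from counting error. Between 2 replicates of 1 age, the chi-square statistic of the counts per degree of freedom lay between 22.1 and 346 over all 50 pairs, so no pair was treated as 1 library deposited again.

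Counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Precursors were kept by edgeR's filterByExpr, which left 425 for testing and set aside 768; the tested precursors held at least 99.9856% of each library's counts. Library sizes were scaled by the trimmed mean of M values (TMM), with factors from 0.952 to 1.04, and levels are given as CPM, the usual read counts scaled to a common library size, with those factors applied. All 25 libraries entered 1 edgeR quasi-likelihood fit with a mean per age and no other term, so that the 5 ages shared 1 estimate of the spread. F tests compared 30 with 2 months and each adjacent pair of ages, any difference among the 5 ages, a linear slope on age (given as log2 change per 12 months) and a departure of the age means from that slope. P-values were adjusted by the Benjamini-Hochberg method over the 425 precursors with a threshold of 0.05. The standard error (SE) of a log2 fold change was computed as its size divided by the square root of the F statistic. Within-lane differences were taken as log2(CPM + 0.5) in the lanes that held both ages. They use the same libraries from which the precursors were picked, so a shared side across lanes is a description and not a separate test.

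The precursors named for 30 against 2 months were the 12 largest rises and the 12 largest falls among those past the threshold with a mean of at least 10 CPM over all libraries. For each adjacent pair of ages the rule took the 4 largest rises and 4 largest falls, for the slope the 6 smallest p-values in each direction, and for the departure the 6 smallest p-values, all with the same CPM minimum. Where none passed, the 3 smallest p-values were named. The 5 most abundant precursors and examples from the lists were named as well. The rule, the lists and the tests were fixed before the data were examined. The examples from the lists were picked after their values were seen, and an early selection had left out members near 0 or with a wide spread; 14 such members were then added.

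There were 17 lists: the miR-29 family, neuron-enriched miRNAs, the activity-regulated miR-132/212 pair, oligodendrocyte, astrocyte-associated, microglia and immune, erythroid, vascular and mural, choroid plexus and ciliated-cell, epithelial and sensory (miR-200 and miR-183 clusters), Hox-cluster, let-7, p53 and senescence, miR-17~92 with paralogs, the Dlk1-Dio3 imprinted cluster, the Sfmbt2-intron cluster, and muscle and liver. The lists name mature miRNAs and were matched to the precursors that carry them. The 15 lists with at least 3 tested members were tested with limma's camera on voom log2 CPM, with a preset inter-gene correlation of 0.01; an estimated correlation and limma's fry rotation test were alternatives. Members were also tested with adjustment over the list alone.

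Names of 1181 precursors matched a gene of the GENCODE M21 annotation of GRCm38, which gave positions; coordinates are 1-based. Identical mature sequences at several loci, or hairpins on opposite strands of 1 locus, can receive the same reads. Of 103 such pairs with at least 100 reads in every library, 34 divided their reads between 49 and 51 percent, so the members of such pairs are not independent measurements. Names below omit the prefix mmu-, with which all names in the count table begin.

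Alternatives planned beforehand were the RLE, upper-quartile and library-total scalings, DESeq2 with its own size factors, limma-voom, edgeR's robust dispersion, no filter, a stricter filter of 10 CPM in at least 5 libraries, a fit with only the 2 ages compared, only the 2-month replicates 3 to 5 (whose animal numbers form a separate series), each library left out in turn, and, for the comparison of early with late changes, another late interval. Lane as a covariate, removal of the 5 libraries of lane 3, and the summing of copies and overlapping loci before the test were chosen after seeing the data.

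The tests were run first on simulated counts drawn with the means, dispersions and library sizes of the 425 precursors, of which 67 were changed by 1.25-fold, 67 by 1.5-fold and 66 by 2-fold. For 30 against 2 months the procedure recovered 53.7%, 88.1% and 92.4% of those changes, and 3.11% of its calls were false. Across the 8 tests the false share ranged from 1.27% to 4.52%, with 0 calls when nothing was changed. In the tests that give a direction, 0 changes were called in the wrong one. The simulated precursors were drawn independently of each other and without a lane effect, so these shares may not carry over to the real libraries.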

Results

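Small RNAs were sequenced from the brain hemispheres of 25 male C57BL/6 mice, 5 at each of 2, 9, 15, 24 and 30 months of age, to follow miRNA levels across adult life. Total counts, in M (mega-reads), averaged 5.37 ± 0.433 M at 2 months, 5.44 ± 1.66 M at 9 months, 6.15 ± 1.89 M at 15 months (SD, n = 5). They averaged 6.23 ± 0.580 M at 24 months and 5.98 ± 2.08 M at 30 months (SD, n = 5). Between 620 and 734 precursors had at least 1 read in a library, and the 10 most abundant precursors held 49.3% to 52.0% of the reads. The most abundant was mir-127, a miRNA of the imprinted Dlk1-Dio3 region, with a mean share of 14.9%. It was followed by mir-22 with 6.00%, mir-181a-1 with 5.47%, mir-181a-2 with 5.41% and mir-30a with 5.03%. Of these, mir-22 fell between 2 and 30 months (log2 fold change -0.24 ± 0.06, SE, adjusted p = 0.00289). The other 4 did not pass the test, with log2 fold changes of -0.10 ± 0.05 for mir-127, 0.06 ± 0.05 for each mir-181a copy and 0.10 ± 0.06 for mir-30a (adjusted p from 0.144 to 0.414). The reads of the mir-181a copies cannot be told apart where their mature sequence is identical.

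The 5 libraries of lane 3, 1 of each age, stood apart from the other 20. The second principal component of log2 CPM held 20.2% of the variance, and lane accounted for 91.4% of that component and age for 9.91%. Age accounted for 28.7% of the first component, which held 38.6% of the variance, and for 87.4% of the third, which held 9.88%. The 8 precursors of the miR-200 and miR-183 clusters weighed most in the first component. In lane 3 let-7j lay between 0.120 and 4.23 CPM, against 19.6 to 222.01 CPM in the other lanes. mir-378d lay between 0.148 and 1.296 CPM against 5.08 to 39.4 CPM. With lane as a covariate, chosen after seeing the data, 98.1% of the 157 precursors called between 2 and 30 months were called again, among 172. Without lane 3, 89.8% of them were called, among 163.

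Between 2 and 30 months, the widest interval of the design, mir-219b and mir-219a-1, of the miR-219 family that promotes oligodendrocyte differentiation, rose the most among precursors with a mean of at least 10 CPM. mir-219b rose from 125.8 ± 8.82 to 378.7 ± 62.2 CPM (SD, n = 5), a log2 fold change of 1.59 ± 0.09 (SE, adjusted p = 4.92e-12). mir-219a-1 rose from 33.5 ± 5.72 to 99.97 ± 13.4 CPM (1.58 ± 0.12, adjusted p = 1.29e-09). mir-219a-2, the most abundant of these loci, rose from 771 ± 43.3 to 1266 ± 161 CPM (0.71 ± 0.07, adjusted p = 3.88e-08). mir-10a, which lies in the Hoxb gene cluster, rose from 257 ± 76.0 to 546 ± 86.5 CPM (1.09 ± 0.17, adjusted p = 2.21e-05). mir-146a, induced by NF-κB in inflammation, rose from 119 ± 21.01 to 236 ± 25.2 CPM (0.99 ± 0.13, adjusted p = 3.90e-06). mir-33, in an intron of Srebf2 and a regulator of cholesterol export, rose by a log2 fold change of 0.62 ± 0.09. The hypoxia-induced mir-210 rose by 0.61 ± 0.09 and mir-203, known from keratinocyte differentiation, by 0.56 ± 0.08 (adjusted p of the 3 from 6.51e-06 to 1.37e-05). mir-449a, a miRNA of multiciliated cells, rose by 0.72 ± 0.17 (adjusted p = 0.00153). The rises of mir-8114 (0.79 ± 0.13), mir-3084-2 (0.75 ± 0.16) and mir-3084-1 (0.69 ± 0.21) lay between 7.49 and 13.7 CPM, and the mir-3084 copies share sequence. The call of mir-3084-1 (adjusted p = 0.0132) was lost without 2-month replicate 1 (0.47, adjusted p = 0.0568), without 30-month replicate 3 (0.59, adjusted p = 0.0541). It was also lost with only the libraries of the 2 ages (adjusted p = 0.0609) and with only 2-month replicates 3 to 5 (0.42, adjusted p = 0.112).

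In the GENCODE M21 annotation of GRCm38, mir-219a-1 lies on chromosome 17 at 34024983 to 34025092 on the minus strand, with mmu-mir-219c opposite it at 34025012 to 34025071. mir-219a-2 lies on chromosome 2 at 29845631 to 29845727 on the minus strand and mir-219b opposite it at 29845647 to 29845711. These 4 loci share sequence, so their reads could be divided among them in the counting. When they were summed, the total rose by a log2 fold change of 0.89 ± 0.06 between 2 and 30 months and by 0.71 ± 0.06 between 24 and 30 months. From 2 to 30 months this was less than the rise of mir-10a (1.09) or mir-146a (0.99), so the lead of the miR-219 loci held only per locus.

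The largest fall among the precursors named by rule was that of mir-296, of the imprinted Gnas locus, which fell from 55.7 ± 4.24 CPM at 2 months to 24.3 ± 4.40 CPM at 30 months (log2 fold change -1.20 ± 0.16, SE, n = 5 per age, adjusted p = 6.51e-06). mir-1983 fell from 40.1 ± 11.2 to 18.02 ± 0.798 CPM (-1.15 ± 0.13, adjusted p = 1.00e-06). Of the Dlk1-Dio3 region, mir-376c fell from 58.8 ± 4.57 to 32.9 ± 1.48 CPM (-0.84 ± 0.10). There mir-381 fell from 7097 ± 856 to 4833 ± 565 CPM (-0.55 ± 0.12) and mir-493 from 14.4 ± 2.89 to 10.1 ± 1.32 CPM (-0.51 ± 0.13). The X-linked neighbours mir-322 and mir-351 fell by log2 fold changes of -0.70 ± 0.10 and -0.65 ± 0.08, to 63.8 ± 8.41 and 117 ± 3.69 CPM. mir-150, abundant in mature lymphocytes, fell from 872 ± 63.7 to 617 ± 48.5 CPM (-0.50 ± 0.07). mir-148a fell from 4109 ± 370 to 2947 ± 386 CPM (-0.48 ± 0.10). mir-670 (-0.76 ± 0.12), mir-6944 (-0.70 ± 0.12) and mir-3086 (-0.56 ± 0.11) completed the 12 named falls, whose adjusted p lay between 1.00e-06 and 0.00323.

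Each of the 24 named precursors lay on the same side in each of the 4 lanes that held both ages. They were picked from these same libraries, as were those of the adjacent ages below, so this is no separate support. Of 425 precursors tested with edgeR, 157 changed between 2 and 30 months, 81 higher and 76 lower at 30 months. The change exceeded 2-fold for 15 of them and 1.5-fold for 37. Of those past 2-fold, only mir-219b, mir-219a-1, mir-10a, mir-296 and mir-1983 had a mean of at least 10 CPM. The rest had lower means, among them mir-467d, mir-467e and mir-669c of the Sfmbt2-intron cluster. Upper-quartile scaling gave 50 higher and 91 lower, so the balance of rises and falls depended on the scaling.

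**Figure D1:**
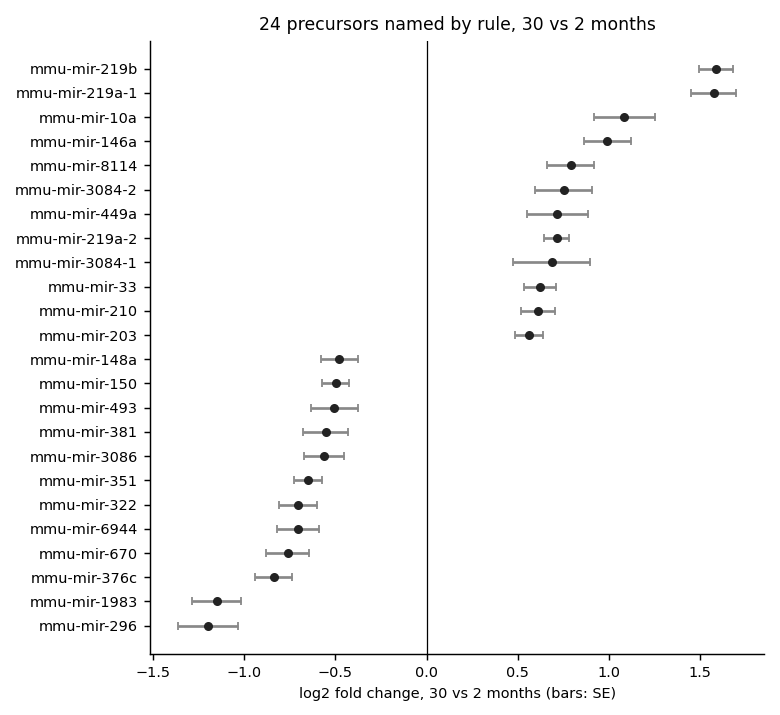
Log2 fold change between 2 and 30 months (horizontal axis) of the 24 precursors named by rule, with bars of 1 SE from the fit to 25 libraries. Values run from -1.20 for mir-296 to 1.59 for mir-219b.

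Of the 17 lists, 15 were large enough to test with camera, and 3 passed between 2 and 30 months: oligodendrocyte miRNAs higher, and the Dlk1-Dio3 and Sfmbt2-intron clusters lower. With an estimated correlation only the Sfmbt2-intron list passed. Other divisions of the same libraries gave up to 7 lists, so chance is not excluded for the number of lists. Not every list member was followed through every setting, and the counts per list below show further losses under other scalings. Several of the members that were followed lost their call between 2 and 30 months under other settings. Under upper-quartile scaling these were mir-29a, mir-29c, mir-34c, mir-92a-1, mir-142a, mir-193a, mir-199a-1, mir-199b, mir-383, mir-434, mir-449c, mir-770 and let-7d (adjusted p from 0.0508 to 0.325), with log2 fold changes of 0.12 for mir-29c and mir-770 and 0.09 for let-7d. With only the 2 ages in the fit they were mir-29a, mir-29c, mir-92a-1, mir-133a-1, mir-193a, mir-199b, mir-383, mir-434, mir-449c, mir-770 and let-7d (adjusted p from 0.0584 to 0.185). With only 2-month replicates 3 to 5 they were mir-29c, mir-34c, mir-128-1, mir-133a-1, mir-146b, mir-193a, mir-199a-1, mir-199b, mir-449c and mir-770 (adjusted p from 0.0513 to 0.304), with log2 fold changes of 0.18 for mir-193a and 0.38 for mir-449c. Without lane 3 the calls of mir-92a-1, mir-193a, mir-199b, mir-434, mir-449c and mir-770 were lost (adjusted p from 0.0558 to 0.168). mir-770 and let-7d were also lost under RLE scaling, with DESeq2 and with the stricter filter, as was mir-29c (adjusted p from 0.0555 to 0.0699). With library totals mir-29c, mir-193a and mir-770 were lost, with the stricter filter mir-434, with DESeq2 mir-449c, and without a filter mir-449c and mir-770 (adjusted p from 0.0508 to 0.0886).

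The 3 tested oligodendrocyte precursors all rose, also adjusted over the list alone and under each of the 4 scalings, with a median log2 fold change of 0.71 (adjusted p = 3.98e-04; adjusted p = 0.0643 with an estimated correlation). They were mir-219a-1, mir-219a-2 and mir-338 (0.54 ± 0.08, SE, n = 5 per age, adjusted p = 1.11e-05), a miRNA of oligodendrocyte differentiation. mmu-mir-338 lies on chromosome 11 at 120014765 to 120014862 with mir-3065 on the opposite strand at 120014767 to 120014853. mir-3065 held 50.04% of the reads of the pair, so their levels are not separate measurements.

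All 14 tested precursors of the Sfmbt2-intron cluster, a large rodent cluster of repeated hairpins, gave a median log2 fold change of -1.07. Of these 9 fell (13 adjusted over the list alone), or 10 to 11 under the other scalings. The list was lower at 30 months (adjusted p = 9.94e-05; adjusted p = 0.00345 with an estimated correlation). mir-467e fell from 7.31 ± 1.82 to 2.26 ± 0.450 CPM (SD, n = 5; log2 fold change -1.65 ± 0.22, adjusted p = 3.98e-06). mir-467d fell by -1.48 ± 0.24 (adjusted p = 3.59e-05) and mir-669c by -1.08 ± 0.17 (adjusted p = 2.21e-05). Most hairpins of this cluster share sequence, and all 3 levels lay near or below 10 CPM.

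Of 49 tested precursors of the Dlk1-Dio3 cluster, 17 fell and 3 rose (17 and 3 adjusted over the list alone), with 21 and 1 under RLE scaling, 22 and 0 under upper-quartile scaling and 19 and 1 with library totals. The median log2 fold change was -0.13 and the list was lower (adjusted p = 0.00104; adjusted p = 0.363 with an estimated correlation). mir-337 fell by -0.39 ± 0.05 (SE, n = 5 per age, adjusted p = 7.41e-06), mir-379 by -0.32 ± 0.06 (adjusted p = 4.46e-04) and mir-411 by -0.28 ± 0.05 (adjusted p = 6.66e-05). The 3 rises were mir-434 (0.22 ± 0.08), mir-770 (0.18 ± 0.06) and mir-3072 (0.42 ± 0.16), with adjusted p from 0.0266 to 0.0377. mir-410 lay at 0.13 ± 0.09 (adjusted p = 0.307). The call of mir-434 was lost in 13 of the 25 refits without 1 library (0.16 to 0.22 over all 25) and that of mir-770 in 18 (0.12 to 0.19 over all 25).

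Among 8 microglia and immune precursors, 5 rose and 1 fell (5 and 1 adjusted over the list alone; 4 and 1 under upper-quartile scaling), with a median of 0.45. The list did not pass (adjusted p = 0.0699; adjusted p = 0.363 with an estimated correlation). Besides mir-146a, mir-155, induced in activated immune cells, rose from 4.23 ± 0.743 to 11.1 ± 3.10 CPM (SD, n = 5; log2 fold change 1.39 ± 0.26, adjusted p = 2.25e-04). The others were mir-21a (0.47 ± 0.07, adjusted p = 1.34e-05), mir-146b (0.48 ± 0.14, adjusted p = 0.00934) and the haematopoietic mir-142a (0.39 ± 0.12, adjusted p = 0.0119). The fall was that of mir-150, and the myeloid mir-223 lay at 0.14 ± 0.20 (adjusted p = 0.629). The call of mir-146b was lost without 2-month replicate 1 (0.34), without 30-month replicate 2 (0.38) or 3 (0.41) and with only 2-month replicates 3 to 5 (0.38). That of mir-142a was lost without 2-month replicate 3 (0.30) or 30-month replicate 5 (0.28) and under upper-quartile scaling (0.32).

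Of 19 neuron-enriched precursors, 6 fell and 1 rose (6 and 1 adjusted over the list alone; 7 and 1 under RLE scaling, 8 and 0 under upper-quartile scaling). The median log2 fold change was 0.02 while the mean was -0.05 and camera pointed lower (adjusted p = 0.380; adjusted p = 0.479 with an estimated correlation). The median was -0.01 under RLE scaling, -0.05 under upper-quartile scaling and -0.01 with library totals. The falls were mir-128-1 (-0.37 ± 0.09, SE, n = 5 per age, adjusted p = 0.00301), mir-128-2 (-0.35 ± 0.09) and mir-137 (-0.23 ± 0.06). The others were mir-153 (-0.20 ± 0.07), mir-138-2 (-0.19 ± 0.06) and mir-138-1 (-0.18 ± 0.06). The rise was mir-383 (0.28 ± 0.08, adjusted p = 0.0116). The abundant neuronal miRNAs mir-124-1 (0.10 ± 0.05, adjusted p = 0.126) and mir-9-1 (0.09 ± 0.08, adjusted p = 0.407) did not pass. The call of mir-128-1 was lost with only 2-month replicates 3 to 5 (-0.26). That of mir-383 was lost without 30-month replicate 3 (0.21), under upper-quartile scaling (0.21) and with only the 2 ages (0.25). Both precursors of the activity-regulated, CREB-induced pair fell, also adjusted over the list alone and under each scaling. mir-212 fell from 890 ± 75.3 to 640 ± 29.3 CPM (-0.48 ± 0.06, adjusted p = 3.90e-06) and mir-132 by -0.34 ± 0.06 (adjusted p = 9.77e-05). A list of 2 was not tested with camera.

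All 4 miR-29 precursors, which target extracellular-matrix genes, rose with TMM scaling and adjusted over the list alone, while 2 rose under RLE scaling, 1 with library totals and 0 under upper-quartile scaling. The median was 0.20 (adjusted p = 0.107; adjusted p = 0.443 with an estimated correlation). The log2 fold changes were 0.25 ± 0.07 for mir-29a, 0.20 ± 0.06 for mir-29b-1, 0.17 ± 0.06 for mir-29b-2 and 0.20 ± 0.07 for mir-29c (SE, n = 5 per age, adjusted p from 0.0105 to 0.0374). The call of mir-29a was lost without 2-month replicate 2 (0.20) or 3 (0.20) and without 30-month replicate 3 (0.19) or 5 (0.15). That of mir-29c was lost in 14 of the 25 refits (0.10 to 0.21 over all 25). Of 13 let-7 precursors, 4 rose and 0 fell (4 adjusted over the list alone; 3 under RLE and upper-quartile scaling), with a median of 0.16 (adjusted p = 0.0614; adjusted p = 0.588 with an estimated correlation). They were let-7i (0.44 ± 0.09, adjusted p = 3.73e-04), let-7f-1 and let-7f-2 (0.38 ± 0.09 each) and let-7d (0.16 ± 0.05, adjusted p = 0.0219). The call of let-7d was lost in 16 of the 25 refits (0.08 to 0.16 over all 25). let-7a-1 lay at 0.08 ± 0.12 and let-7g at 0.05 ± 0.10, and both passed without lane 3 (0.24 and 0.19). let-7j, low in lane 3, lay at 1.246 ± 1.24.

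In the choroid plexus and ciliated-cell list 3 of 6 tested precursors rose (3 adjusted over the list alone; 1 under upper-quartile scaling), with a median of 0.31 (adjusted p = 0.107; adjusted p = 0.363 with an estimated correlation). They were mir-449a, mir-449c (0.61 ± 0.21, SE, n = 5 per age, adjusted p = 0.0250) and mir-34c (0.27 ± 0.08, adjusted p = 0.0152), all of multiciliated cells. mir-204, abundant in choroid plexus, lay at 0.15 ± 0.08 (adjusted p = 0.159). The call of mir-449c was lost in 7 of the 25 refits (0.38 to 0.75 over all 25) and that of mir-34c in 6 (0.20 to 0.29 over all 25). Of the Hox-cluster list 2 precursors were tested, of which mir-10a rose, also adjusted over the list alone, and mir-10b lay at 0.36 ± 0.22 (adjusted p = 0.220).

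Of 7 vascular and mural precursors 2 rose (3 adjusted over the list alone; 0 under upper-quartile scaling), with a median of 0.19 (adjusted p = 0.437; adjusted p = 0.588 with an estimated correlation). They were the mesenchymal mir-199a-1 (0.27 ± 0.08, SE, n = 5 per age, adjusted p = 0.0159) and mir-199b (0.30 ± 0.10, adjusted p = 0.0235). The endothelial mir-126a (0.02 ± 0.04, below 0 under the other 3 scalings), mir-143 (-0.00 ± 0.05) and mir-145a (-0.10 ± 0.11) of smooth muscle did not pass. The call of mir-199a-1 was lost without 2-month replicate 2 (0.21) or 3 (0.22) or 30-month replicate 5 (0.19). That of mir-199b was lost in 6 of the 25 refits (0.20 to 0.38 over all 25). Of 6 astrocyte-associated precursors 1 rose (0 adjusted over the list alone, and 0 under upper-quartile scaling and with library totals), with a median of 0.13 (adjusted p = 0.286; adjusted p = 0.443 with an estimated correlation). It was mir-193a (0.39 ± 0.14, adjusted p = 0.0287), whose call was lost in 14 of the 25 refits (0.27 to 0.51 over all 25). mir-24-2 lay at 0.18 ± 0.07 (adjusted p = 0.0579), passing without 2-month replicate 4 (0.22) and with the lane covariate (0.19). mir-27a lay at 0.10 ± 0.12 and mir-23a at 0.03 ± 0.06, or -0.04 under upper-quartile scaling.

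The p53 and senescence list had 3 falls and 0 rises among 7 (3 and 0 adjusted over the list alone and under each scaling), with a median of -0.04 (adjusted p = 0.380; adjusted p = 0.479 with an estimated correlation). mir-22, mir-194-2 (-0.30 ± 0.09, SE, n = 5 per age, adjusted p = 0.0143) and mir-194-1 (-0.28 ± 0.10, adjusted p = 0.0318) fell. The p53 targets mir-34a (0.19 ± 0.09, adjusted p = 0.100) and mir-192 (-0.04 ± 0.07, adjusted p = 0.691) did not pass. Of 12 precursors of miR-17~92 and its paralogs 2 rose and 2 fell (2 and 2 adjusted over the list alone; 1 and 2 under upper-quartile scaling), with a median of -0.06 (adjusted p = 0.732; adjusted p = 0.853 with an estimated correlation). mir-93 (0.35 ± 0.06, adjusted p = 3.18e-05) and mir-92a-1 (0.22 ± 0.08, adjusted p = 0.0267) rose. mir-20a (-0.46 ± 0.12, adjusted p = 0.00513) and mir-17 (-0.29 ± 0.08, adjusted p = 0.00690) fell. The call of mir-92a-1 was lost in 14 of the 25 refits (0.12 to 0.23 over all 25).

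None of 4 erythroid precursors passed (0 adjusted over the list alone; median 0.34, adjusted p = 0.541; adjusted p = 0.847 with an estimated correlation). mir-451a lay at 0.51 ± 0.34, mir-144 at 0.79 ± 0.36 (adjusted p = 0.0828) and mir-486a at 0.18 ± 0.26 (SE, n = 5 per age). mir-144 passed without 9-month replicate 1 (0.75) and with only the 2 ages (0.76). Of 9 muscle and liver precursors 2 rose and 0 fell (2 and 0 adjusted over the list alone; 2 and 1 under RLE scaling and 1 and 1 under upper-quartile scaling). The median was 0.16 and camera pointed higher (adjusted p = 0.732; adjusted p = 0.853 with an estimated correlation), while the mean was -0.01. The muscle miRNAs mir-133a-1 (0.31 ± 0.08, adjusted p = 0.00278) and mir-133a-2 (0.25 ± 0.08, adjusted p = 0.0116) rose. mir-1a-1 lay at -0.50 ± 0.20 (adjusted p = 0.0536) and passed in 16 of the 25 refits (-0.59 to -0.46 over all 25), under RLE (-0.53) and upper-quartile scaling (-0.57), with only the 2 ages (-0.53) and with only 2-month replicates 3 to 5 (-0.63). The call of mir-133a-1 was lost with only the 2 ages (0.28) and with only 2-month replicates 3 to 5 (0.20).

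None of the 8 precursors of the miR-200 and miR-183 clusters, known from epithelial and sensory cells, passed (0 adjusted over the list alone), and the list did not (median log2 fold change 0.57, adjusted p = 0.712; adjusted p = 0.853 with an estimated correlation). mir-182 ranged from 210 to 4464 CPM among the 2-month libraries and from 822 to 5983 CPM among the 30-month libraries, so an age difference was not detectable (0.79 ± 0.97, SE, n = 5 per age, adjusted p = 0.563). mir-200a lay at 0.42 ± 0.99, or -0.09 with the lane covariate, and mir-200b at -0.06 ± 0.74, or 0.50 without lane 3.

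**Figure D2:**
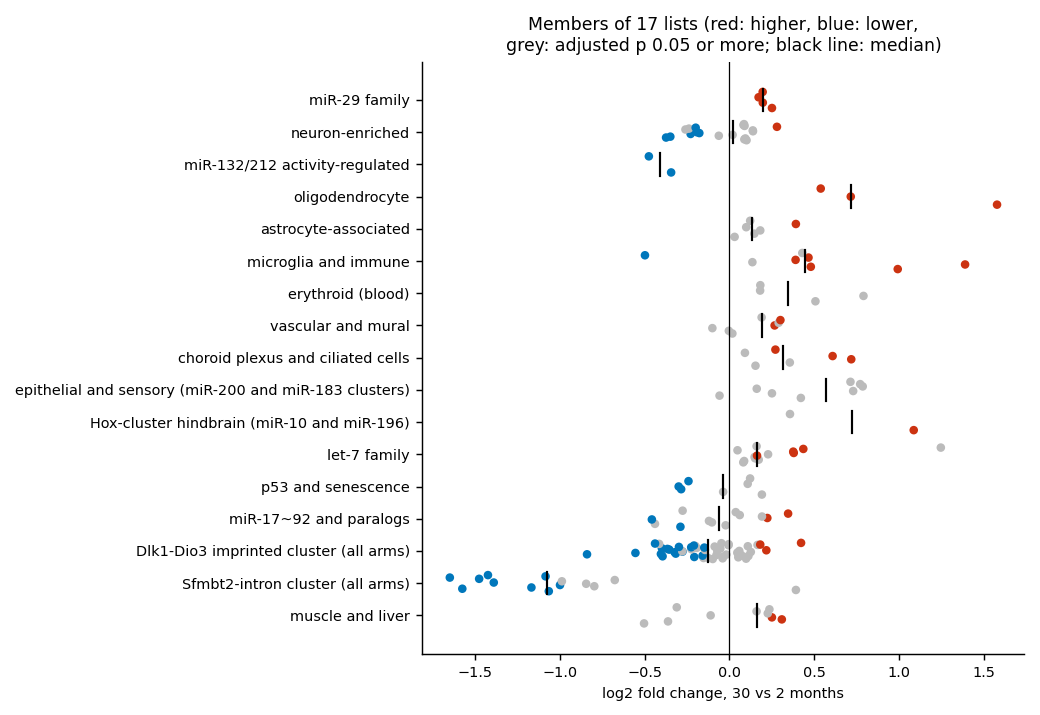
Log2 fold change between 2 and 30 months (horizontal axis) of each tested precursor in the 17 lists, red where higher and blue where lower with adjusted p below 0.05 and grey otherwise; black lines mark list medians. The median of the Sfmbt2-intron list lies at -1.07 and that of the oligodendrocyte list at 0.71.

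**Figure D3:**
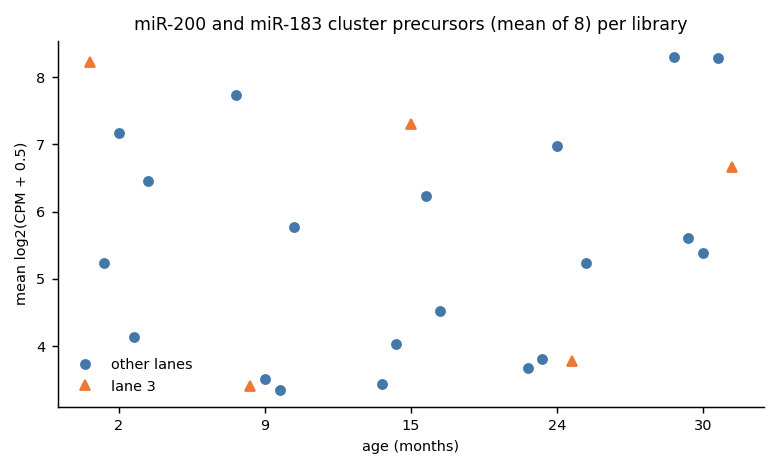
Mean log2(CPM + 0.5) of the 8 precursors of the miR-200 and miR-183 clusters (vertical axis) in each of the 25 libraries, arranged by age. Orange triangles mark the libraries of lane 3 and blue points those of other lanes. The mean runs from 4.14 to 8.22 among the 5 libraries of 2 months.

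Between 2 and 9 months the largest named rise was that of mir-152, of the miR-148 family, from 31.1 ± 2.73 to 40.3 ± 5.48 CPM (SD, n = 5; log2 fold change 0.37 ± 0.09, adjusted p = 0.0138). mir-29b-1 rose from 634 ± 72.2 to 815 ± 26.3 CPM (0.36 ± 0.06) and mir-29b-2, with the same mature sequence, by 0.35 ± 0.06 (adjusted p = 0.00124 each). mir-101a, which targets Ezh2, rose from 5993 ± 247 to 7362 ± 608 CPM (0.30 ± 0.05, adjusted p = 6.43e-04). mir-296 fell from 55.7 ± 4.24 to 29.9 ± 6.43 CPM (-0.90 ± 0.16, adjusted p = 0.00124) and mir-1983 by -0.72 ± 0.13 (adjusted p = 0.00124). mir-322 fell from 104 ± 10.5 to 75.0 ± 9.71 CPM (-0.47 ± 0.10, adjusted p = 0.00562) and mir-412 by -0.47 ± 0.12 (adjusted p = 0.0178). All 8 lay on the same side in each of the 4 lanes that held both ages.

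In total 33 precursors changed between 2 and 9 months, 8 higher and 25 lower. The number was 20 without 2-month replicate 1, 19 without replicate 2, 19 without replicate 5, 20 without 9-month replicate 1 and 21 without 24-month replicate 4. It was 15 without a filter, 9 with only the 2 ages, 9 with only 2-month replicates 3 to 5 and 50 with the lane covariate. The call of mir-412 was lost without 2-month replicate 1 (-0.42) or 2 (-0.37), 9-month replicate 2 (-0.38), a filter (-0.45) or lane 3 (-0.34). It was also lost with only the 2 ages (adjusted p = 0.125) and with only 2-month replicates 3 to 5 (-0.23). mir-152 and mir-1983 were lost with only the 2 ages (adjusted p = 0.0983 and 0.0504), and mir-152 and mir-322 with only 2-month replicates 3 to 5 (adjusted p = 0.0557 and 0.0761).

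Between 9 and 15 months no precursor passed with edgeR. The smallest p-values were those of mir-203, from 176 ± 14.8 to 220.7 ± 9.22 CPM (SD, n = 5; log2 fold change 0.33 ± 0.08, adjusted p = 0.0980), and mir-212, from 732 ± 33.8 to 614.6 ± 55.1 CPM (-0.25 ± 0.06, adjusted p = 0.0980). They were followed by mir-6944 (-0.40 ± 0.12, adjusted p = 0.206), and each lay on the same side in each of the 4 lanes that held both ages. The count was 0 with edgeR, with 27 at an unadjusted p under 0.05, 2 with DESeq2 (mir-203 and mir-212, adjusted p = 0.0153 each) and 0 with limma-voom. With library totals mir-212 passed (adjusted p = 0.0491), as it did without 15-month replicate 2 (-0.29, adjusted p = 0.0390). On simulated counts 82.1% of 1.5-fold and 89.4% of 2-fold changes were recovered in this interval.

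Between 15 and 24 months 1 precursor passed: mir-378a, in an intron of Ppargc1b, fell from 1532 ± 82.3 to 1261 ± 75.1 CPM (SD, n = 5; log2 fold change -0.28 ± 0.06, adjusted p = 0.0318) and lay lower in each of the 4 lanes that held both ages. Its mean at 30 months was 1451 ± 83.6 CPM. The call was lost without 15-month replicate 3 (-0.26, adjusted p = 0.0641), 24-month replicate 1 (-0.26, adjusted p = 0.0621) or 24-month replicate 4 (-0.29, adjusted p = 0.0506). It was also lost under upper-quartile scaling (-0.23, adjusted p = 0.157), without a filter (adjusted p = 0.0523) and without lane 3 (-0.26, adjusted p = 0.0836). DESeq2 called 2 precursors, mir-378a and mir-298, and edgeR with the lane covariate 2, mir-378a and mir-322. mir-298 and mir-322 are named here after their values were seen.

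Between 24 and 30 months the largest named rises were those of mir-219b and mir-219a-1. mir-219b rose from 159 ± 13.0 to 378.7 ± 62.2 CPM (SD, n = 5; log2 fold change 1.248 ± 0.09, adjusted p = 6.68e-10) and mir-219a-1 from 43.3 ± 7.51 to 99.97 ± 13.4 CPM (1.21 ± 0.12, adjusted p = 1.87e-07). mir-33 rose by 0.63 ± 0.09 to 79.1 ± 3.81 CPM (adjusted p = 3.84e-05). mir-219a-2 rose from 856 ± 45.1 to 1266 ± 161 CPM (0.57 ± 0.07, adjusted p = 2.84e-06). The largest named falls were mir-20a of the miR-17~92 cluster (-0.49 ± 0.12, adjusted p = 0.0163) and mir-135b (-0.39 ± 0.11, adjusted p = 0.0288). They were followed by mir-135a-2 (-0.36 ± 0.10, adjusted p = 0.0241) and mir-495 of the Dlk1-Dio3 region (-0.32 ± 0.10, adjusted p = 0.0460). All 8 lay on the same side in each of the 4 lanes that held both ages.

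In total 37 precursors changed between 24 and 30 months, 26 higher and 11 lower, against 11 and 19 under upper-quartile scaling, 20 and 23 with library totals and 27 and 19 with DESeq2. The number was 23 without 24-month replicate 2, 16 without replicate 5, 17 without 30-month replicate 3, 18 without replicate 4, 20 without a filter and 19 with only the 2 ages. The call of mir-135b was lost without 24-month replicate 2 (-0.40) or 5 (-0.36) or 30-month replicate 3 (-0.35), 4 (-0.42) or 5 (-0.37). That of mir-135a-2 was lost without 24-month replicate 5 (-0.30) or 30-month replicate 3 (-0.36), 4 (-0.35) or 5 (-0.36). That of mir-495 was lost without 24-month replicate 4 (-0.24) or 5 (-0.30) or 30-month replicate 2 (-0.35), 3 (-0.28) or 4 (-0.32). With only the 2 ages all 4 falls were lost (adjusted p = 0.0583 for mir-20a, 0.0595 for mir-135b and mir-135a-2, 0.118 for mir-495). mir-135b and mir-495 were also lost without a filter (adjusted p = 0.0606 and 0.0638) and without lane 3 (adjusted p = 0.0671 and 0.0798).

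**Figure D4:**
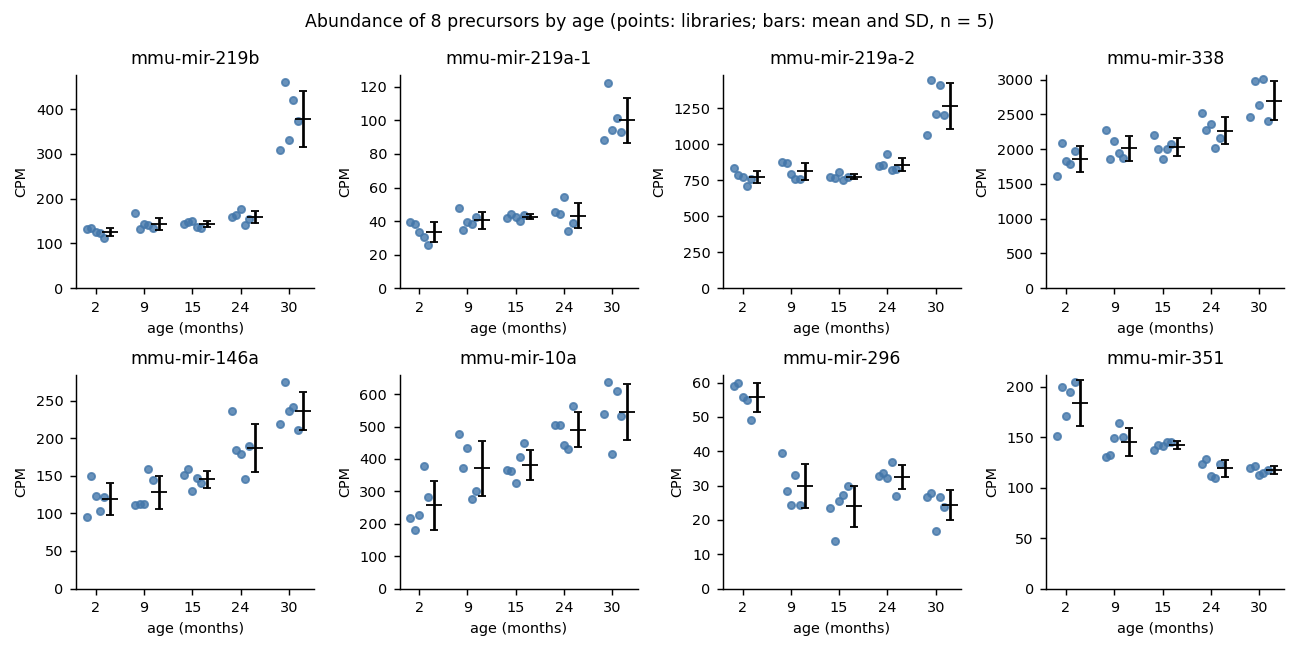
CPM (vertical axis) against age in months for mir-219b, mir-219a-1, mir-219a-2, mir-338, mir-146a, mir-10a, mir-296 and mir-351; points are libraries and bars the mean and SD of 5. mir-219b stays between 125.8 and 159 CPM on average up to 24 months and reaches 378.7 CPM at 30 months.

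Over all 5 ages, mir-146a rose by a log2 change of 0.43 ± 0.05 per 12 months (SE, n = 25, adjusted p = 8.01e-07), with means of 119, 127.98, 145.3, 187 and 236 CPM from the youngest to the oldest age. mir-219b (0.59 ± 0.08), mir-219a-1 (0.57 ± 0.08), mir-3065 (0.21 ± 0.03), mir-488, in an intron of Astn1 (0.19 ± 0.02), and mir-93, of the Mcm7 cluster (0.15 ± 0.02), followed. mir-351 fell by -0.27 ± 0.03 per 12 months (adjusted p = 8.01e-07) and its neighbour mir-322 by -0.29 ± 0.04. mir-376c (-0.33 ± 0.04) and mir-337 (-0.15 ± 0.02) of the Dlk1-Dio3 region, mir-670 (-0.31 ± 0.05) and mir-1983 (-0.42 ± 0.06) also fell. Of 425 precursors 151 had a slope, 83 upward and 68 downward. The split was 62 and 79 under RLE scaling, 54 and 72 under upper-quartile scaling and 62 and 79 with DESeq2. Any difference among the ages was found for 139.

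By list, the slopes were upward for oligodendrocyte (adjusted p = 0.00737; adjusted p = 0.253 with an estimated correlation), microglia and immune (adjusted p = 0.0259; adjusted p = 0.253 with an estimated correlation) and choroid plexus and ciliated-cell precursors (adjusted p = 0.0436; adjusted p = 0.253 with an estimated correlation). They were downward for the Dlk1-Dio3 list (adjusted p = 0.00913; adjusted p = 0.435 with an estimated correlation) and the Sfmbt2-intron list (adjusted p = 7.24e-05; adjusted p = 0.0376 with an estimated correlation), in which 11 of 14 fell. The miR-17~92 list had a median slope of -0.02 while camera pointed upward (adjusted p = 0.916).

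A departure from a straight line was found for 30 precursors. mir-219b averaged 125.8 to 159 CPM up to 24 months and 378.7 CPM at 30 months (adjusted p = 3.47e-07). mir-219a-1 averaged 33.5 to 43.3 CPM and then 99.97 CPM (adjusted p = 1.73e-04), and mir-219a-2 averaged 771 to 856 CPM and then 1266 CPM (adjusted p = 2.09e-04). mir-29b-1 averaged 634, 815, 827, 791 and 726 CPM over the 5 ages and mir-29b-2 followed the same course (adjusted p = 0.00127 each). mir-101a averaged 5993 CPM at 2 months and 7338 to 7827 CPM later (adjusted p = 0.00187). The number was 19 without 30-month replicate 4, under upper-quartile scaling and without a filter, and 53 with the lane covariate.

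Changes between 2 and 9 months and between 15 and 30 months shared no library. Across the 425 precursors, which are not independent replicates, their estimates showed little correlation (Spearman's rho 0.0665, jackknife SD 0.0948 over libraries). The value was 0.0207 with the lane covariate and 1.92e-04 with 24 to 30 months as the late interval. Only 33 of the 425 precursors passed between 2 and 9 months. Noise in the estimates pulls rho toward 0, so a low rho does not show that early and late changes are unrelated.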

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

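Of the tests in this part, that of other precursors moving with the miR-200 and miR-183 clusters was chosen before its result was seen; those of age, of lane and of the 3 loci moving together were chosen only after the result was seen. Of the groups of 5 libraries, 5 for each of 98 precursors and for the total count, 48 had a highest or lowest library whose gap to the nearest of the others exceeded 0.71 of the whole range. Chance gives about 1 in 20 groups. The 48 came from 16 libraries, and 25 of them from the 5 libraries of lane 3, which stood apart from the other 20. Those libraries were 2-month replicate 1, with 8 the most in 1 library, 9-month replicate 2, 15-month replicate 3, 24-month replicate 4 and 30-month replicate 5.

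In 2-month replicate 1, mir-3084-2 was at 4.44 CPM (the others 8.37 to 9.11), mir-203 at 170 CPM (132.6 to 140), and mir-381 at 8612 CPM (6561 to 6839). There mir-493 was at 19.4 CPM (12.4 to 13.8), mir-30a at 40938 CPM (46957 to 48986), mir-486a at 827 CPM (1313 to 1509), let-7a-1 at 8026 CPM (4720 to 5456) and let-7g at 9332 CPM (6002 to 6599). In 2-month replicate 2, mir-488 was at 412.4 CPM (356 to 371) and mir-467e at 10.5 CPM (6.18 to 6.85). In 9-month replicate 2, mir-148a was at 4491 CPM (3348 to 3603), mir-9-1 at 10366 CPM (11454 to 11854), let-7d at 2569 CPM (2789 to 2876) and mir-410 at 15799 CPM (10514 to 11810). In 9-month replicate 4, mir-223 was at 11.3 CPM (11.8 to 12.01).

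In 15-month replicate 3, mir-381 was at 7723 CPM (5437 to 6014), mir-150 at 809 CPM (715 to 729), mir-21a at 3119 CPM (3678 to 3757) and mir-126a at 6905 CPM (6364 to 6501), and in 15-month replicate 4 mir-155 was at 7.58 CPM (5.09 to 5.45). In 24-month replicate 1, mir-155 was at 17.8 CPM (6.89 to 8.87). In 24-month replicate 4, mir-30a was at 44734 CPM (50091 to 52249.7), mir-199b at 36.2 CPM (30.1 to 31.1), mir-143 at 20911 CPM (23089 to 23809) and mir-27a at 825 CPM (472 to 571), and in 24-month replicate 5 mir-10b was at 931 CPM (489 to 554).

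In 30-month replicate 5 the total was 9.52 M reads (the others 4.08 to 5.66 M), and there mir-6944 was at 42.2 CPM (30.2 to 33.1), mir-148a at 3624 CPM (2721 to 2912), mir-488 at 602 CPM (487.3 to 515) and mir-410 at 15257 CPM (11540 to 12491). In 30-month replicate 1, mir-383 was at 538 CPM (677 to 733), in replicate 2 mir-93 at 741 CPM (708 to 710) and mir-770 at 91.8 CPM (81.3 to 83.1), and in replicate 3 mir-3086 at 20.6 CPM (15.8 to 17.04).

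Of the erythroid precursors, mir-451a was at 1275 CPM in 9-month replicate 1 (252.2 to 547), 564 CPM in 15-month replicate 1 (251 to 317) and 850 CPM in 24-month replicate 3 (423 to 500). mir-144 was at 283 CPM (62.1 to 113), 144.2 CPM (53.5 to 76.97) and 248 CPM (96.4 to 119) in the same 3 libraries. mir-486a was at 3131 CPM in 9-month replicate 1 (1106 to 1671).

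The miR-200 and miR-183 clusters were also high in 9-month replicate 1 and 24-month replicate 3. There mir-200a was at 283 CPM (11.9 to 85.7) and 181 CPM (11.4 to 43.5), mir-200b at 135.1 CPM (14.5 to 47.5) and 83.4 CPM (14.8 to 33.4), and mir-182 at 3859 CPM (131 to 940) and 2199 CPM (185 to 649). The clusters did not follow the erythroid precursors throughout. In 15-month replicate 1 their mean log2 CPM was 3.44, the lowest of that age. Across the 25 libraries it was highest in 30-month replicates 1 and 4 (8.29 and 8.28) and 2-month replicate 1 (8.22). No erythroid precursor named above stood out as high there, and mir-486a was low in 2-month replicate 1 (827 CPM). Of the variance of the clusters' mean log2 CPM 82.6% lay within lanes, which argues against lane as the main cause. Within ages lay 73.6%, but the pattern was picked as a spread within ages, so this share decides nothing about age. The 3 loci moved together within ages, with a smallest Pearson r of 0.978 (Spearman's rho 0.938, 25 libraries, permutation p = 1e-05 each, the smallest that could be reached, and 1e-05 adjusted over 3 relations; r = 0.970 without the 2 farthest libraries), so a common source or regulator may lie behind them. RNA of another tissue could be such a source, but 0 of 417 other precursors rose with the 8 at an adjusted p below 0.05 in edgeR, with age and lane in the model (24 at an unadjusted p under 0.05, in either direction). Carry-over seen outside these clusters was thus not detected, but how much of it this test could have missed was not measured. No tissue was tested as the source, and a difference between animals stays open.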

How the results depend on the processing

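Lane as a covariate, removal of lane 3 and summing of copies were chosen after seeing the data; the other alternatives were planned. Of 4139 values of 113 named results under the alternatives, 3828 kept their direction and side of the threshold, 220 fell short of it, 30 passed it newly and 61 changed sign, 42 of these when 1 library was left out. The count for 2 against 30 months lay between 119 and 172 under all other settings, and those among the ages and of slopes stayed within 1.5 times their values. The cause of the differences below was not tested, except that fits without a filter adjust over more precursors and fits with only the 2 ages or fewer libraries hold fewer samples.

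Upper-quartile scaling gave 0 calls for 15 to 24 months and 19 departures from a line, and library totals gave 1 call for 9 to 15 months. DESeq2 gave 2 for 9 to 15 and 2 for 15 to 24 months. Without a filter there were 15 calls for 2 to 9 months, 0 for 15 to 24, 20 for 24 to 30 and 19 departures. With only the 2 ages in the fit there were 9 for 2 to 9 and 19 for 24 to 30 months, and with only 2-month replicates 3 to 5 there were 9 for 2 to 9 months. With an estimated correlation 1 list passed for 2 to 30 months and 1 for the slope, and with fry, which tests each list on its own, 9 and 8. The lane covariate gave 50 calls for 2 to 9 months, 2 for 15 to 24 months and 53 departures, and removal of lane 3 gave 0 for 15 to 24 months.

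Leaving out each library in turn gave 131 to 163 calls for 2 to 30 months, 19 to 39 for 2 to 9, 0 to 1 for 9 to 15, 0 to 1 for 15 to 24 and 16 to 53 for 24 to 30 months. It gave 121 to 152 slopes, 19 to 39 departures, 3 to 4 and 4 to 5 lists, and a rho of early with late changes of 0.0104 to 0.117.

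Sign changes between 2 and 30 months were all of precursors that had not passed. mir-126a was at -0.01002 under RLE scaling, -0.0498 under upper-quartile scaling, -0.00895 with library totals, -0.00986 with DESeq2 and -0.0173 with the stricter filter. It was at -0.0144 with only the 2 ages, -0.00535 with only 2-month replicates 3 to 5 and -0.0465 without lane 3. mir-23a was at -0.0387 under upper-quartile scaling, -0.00353 with the stricter filter, -3.40e-04 with only the 2 ages, -0.00304 with only 2-month replicates 3 to 5 and -0.00443 without lane 3. let-7g was at -0.0255 under upper-quartile scaling, mir-143 at 6.89e-04 without a filter and mir-486a at -0.0120 with only 2-month replicates 3 to 5. mir-200b was at 0.13 with only 2-month replicates 3 to 5 and 0.50 without lane 3, and mir-200a at -0.0874 with the lane covariate. With 1 library left out, mir-126a ranged from -0.0491 to 0.0216, mir-143 from -0.0683 to 0.0172, mir-23a from -0.0303 to 0.0565 and mir-27a from -0.0136 to 0.126. let-7g ranged from -0.0353 to 0.130, mir-223 from -0.0414 to 0.302 and mir-200b from -0.56 to 0.36.

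No paired analysis was possible because replicate numbers follow the order of deposition and each title carries its own animal number; libraries of different ages were matched only by lane, as a covariate and within lanes. With libraries of 3.78 to 9.52 M reads, 768 precursors were too low to test. Changes of 1.5-fold were recovered in 74.6% to 89.6% of simulated cases. Many precursors were changed at once in the simulation, so recovery would be lower where few change.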

Other observations

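The genomic clusters and summed loci in this part, and all tests here except the splits of the libraries for the 2 numbers of lists, were chosen only after the result was seen.

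Precursors were grouped by genomic position into clusters of neighbours within 10000 bp, of which 16 had at least 3 tested members and 3 passed camera between 2 and 30 months. On chromosome X at 53047997 to 53054349 (GENCODE M21) all 6 tested precursors fell: mir-322, mir-351, mir-450a-1, mir-450a-2, mir-450b and mir-542, with a median log2 fold change of -0.73 (adjusted p = 1.03e-04; adjusted p = 0.00167 with an estimated correlation). On chromosome 2 at 10473931 to 10514395, 9 of 13 Sfmbt2-intron precursors fell, with a median of -1.08 (adjusted p = 2.05e-05; adjusted p = 0.00167 with an estimated correlation). On chromosome 12 at 109709060 to 109747960, 16 of 36 Dlk1-Dio3 precursors fell and 1 rose, with a median of -0.18 (adjusted p = 2.59e-04; adjusted p = 0.188 with an estimated correlation).

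After copies with shared sequence were summed, mir-344-1 with mir-344-2 rose by a log2 fold change of 0.46 ± 0.09 between 2 and 30 months (SE, n = 5 per age, edgeR adjusted p = 3.51e-04) and the 3 mir-344d copies by 0.41 ± 0.10 (adjusted p = 0.00295). The summed mir-181b copies rose by 0.33 ± 0.06, the mir-450a copies fell by 0.84 ± 0.13 on the log2 scale and mir-374b with mir-374c by 0.38 ± 0.08. mir-338 with mir-3065 rose by 0.52 ± 0.08.

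mir-219a-1 and mir-219b rose more than mir-219a-2 between 24 and 30 months, and the log2 ratios to mir-219a-2 shifted by 0.66 and 0.68 (n = 5 per age, exact permutation p = 0.00794 each, 2-sided, the smallest possible, for loci picked for this rise). Both ratios shifted upward in each of the 4 lanes that held both ages, the least by 0.31. The smallest possible exact p already fixed this direction, so it is no separate support for the rise. Within such a lane both libraries share the lane, so lane alone does not account for the shift there. More oligodendrocyte RNA in the 30-month samples may contribute to a common rise of these loci. mir-338, of the oligodendrocyte list, rose by 0.25 ± 0.08 (SE, n = 5 per age, edgeR adjusted p = 0.0444), less than mir-219a-1. It also rose less than mir-219a-2, with a shift of their log2 ratio of -0.31 (exact permutation p = 0.00794). Summed with mir-3065, on the opposite strand, it rose by 0.23 ± 0.08 and did not pass (edgeR adjusted p = 0.0717). How much of mir-338 comes from other cells was not measured, so more oligodendrocyte RNA stays open for a common rise. The rise of mir-338 does not bear on why mir-219a-1 and mir-219b rose more than mir-219a-2. The ratio of mir-219b to mir-219a-1 shifted by 0.0214, but these loci were picked for their similar rise, so whether reads of 1 mature sequence were assigned to several loci also stays open. Age, which the design names, stays open as a cause, since the shift between the 2 ages is the pattern itself and no separate test of age was made.

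The 5 libraries of lane 3 stood apart on the second principal component, with 61 precursors higher and 60 lower in lane 3 in edgeR. A line on log2 total count through the other 20 libraries gave -0.306% of the gap between lane 3 and the others (95% bootstrap interval -19.6% to 11.7%, 10000 resamples), which argues against library depth as the main cause. Lane 3 held 1 library of each age, so it is not confounded with age, and no biological explanation was tested. What differed in that lane is not given in the sources used here, and the cause stays open.

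In each of 100 divisions of the libraries drawn for a test, the real one included, the number of calls was counted. For 2 to 30 months the real number was 157 and the highest other 54 (1 of 100 as large). It was 33 against 21 for 2 to 9 months (1) and 37 against 7 for 24 to 30 months (1). Any age difference gave 139 against 9 (1), slopes 151 against 49 (1) and departures 30 against 8 (1). Each of these counts was larger than in any other division drawn. A share of 1 of 100 was the smallest that could be reached, so chance is made unlikely but not excluded. For 15 to 24 months the real number was 1 and the highest other also 1, with 3 of 100 as large. That share is under 0.05, but other divisions also reached this count of 1 precursor, so chance is not excluded for it. The precursor was mir-378a, whose log2 fold change lay between -0.29 and -0.23 in the alternatives that ended its call. For 9 to 15 months the real number was 0 and 100 of 100 were as large. For lists, 46 of 100 divisions gave as many as the 3 found for 2 to 30 months and 6 of 100 as many as the 5 found for the slope, with a highest other of 7 each, so chance is not excluded for either number.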
